A study of Mus musculus with 12 samples.

How the data were processed

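RNA of EML1 progenitor cells with the empty lentiviral vector pWPI or with TEL-AML1 in pWPI was measured on 12 arrays, 2 for each of 6 groups: untreated, day 5 and day 7 of IL7 and FLT3L for each vector. Groups and replicate numbers were taken from the sample titles, and all 12 arrays entered the comparisons. Per the labels' protocols, total RNA was extracted with TRIzol and cleaned on RNeasy columns, and biotin-labelled cRNA was hybridised by the standard Affymetrix procedure. Each array in the deposited table has 1 linear intensity per probe set, for 35556 probe sets, with values from 15.162 to 7932.3. How the authors corrected the background, summarised probes and normalized the arrays is not given in the sources used here. The medians of the log2 arrays lay within 0.0795 of each other, under a limit of 0.5 set for renormalization, so the deposited intensity values were kept as they stood. An array has no read depth, and its brightness over background and the number of arrays limit the precision of each value.

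Probe sets were named through the platform annotation table: 21218 listed 1 gene, 1881 listed several and 12457 were not listed, and names were given only to the first kind. Of those, 21185 matched an entry of the GRCm38.p6 gene table by Entrez identifier, and 0 symbols changed. That table also supplied each gene's chromosome and order, and its coordinates were not used because the build behind the array annotation is not given in the sources used here. Control probe sets could not be told from others by name and stayed in the percentiles. The 18820 named genes were each represented by the probe set with the highest mean over all arrays. For 1386 genes with several probe sets, called probe sets disagreed in direction for 1 gene, in the day 7 comparison of the empty vector. Genes were kept if their mean intensity passed the 40th percentile of all probe sets (59.9), which left 12345 genes for testing.

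Values were transformed as log2(intensity + 16), so that fold changes of dim genes are understated. One model of 6 group means was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 residual and 4.23 prior degrees of freedom. It gave 12 contrasts: TEL-AML1 against empty vector in each condition and in their mean, day 5 and day 7 against untreated and day 7 against day 5 in each vector, and the difference between the vectors' responses at day 5 and at day 7. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. The median standard error of a difference between groups was 0.0989 on the log2 scale. Gene lists were fixed for 25 groups: B lineage, lymphoid priming, stem and progenitor, erythroid, megakaryocyte, granulocyte, monocyte and macrophage, dendritic and antigen presentation, mast with basophil and eosinophil, T and NK, OP9 stroma, adipocyte, cell cycle, p53 targets, apoptosis, interferon, TGF-beta and BMP, retinoic acid, JAK-STAT, RUNX1-linked, immediate early, sterol synthesis, hypoxia and glycolysis, ER and integrated stress, and adhesion and homing. Of the 38 B lineage genes, 36 had a probe set and 21 passed the filter, and of the 40 stroma genes, 39 and 34. The lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with an estimated correlation. A rotation test, fry, asked whether the genes of a list move one way on balance. Members were also adjusted over their own list alone. Of the interferon calls of treated against untreated cells, those of day 5 in both vectors and of day 7 with TEL-AML1 held with an estimated correlation, and no other camera call did.

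The contrasts, tests, filter, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named genes were the 15 highest and 15 lowest fold changes of a contrast among called genes whose arrays of one side all lay above the other (10 each way for day 7 against day 5 and for the differences between responses), skipping clone and predicted names. To these came up to 6 members with the smallest adjusted p of each list, called or not, whose values could be given in other contrasts too, and Etv6, Runx1, Runx2, Runx3, Cbfb, Rara and Epor. From these a part was given, picked after the values were seen, with preference for calls that held without each single array. The genes of distal chromosome 5 and chromosome Y were singled out after their values were seen. Bright genes are those with a mean over 8 on the log2 scale. The distal stretch starts at the split of bright chromosome 5 genes that left the least absolute deviation from both parts' medians. The mean TEL-AML1 contrast was used for this.

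The alternatives fixed beforehand were quantile normalization, centring on array medians, no filter and a filter at the 60th percentile, pseudocounts of 1 and 64, the mean of a gene's probe sets and every probe set by itself, a trended and robust variance, array weights, only the compared groups, the replicate number as a block, each array's mean over the stroma list as a covariate, and leaving out each array in turn. Whether replicate numbers pair arrays was checked by correlating deviations from the group means. Arrays with the same number in TEL-AML1 and empty-vector cells of a condition deviated together (r = 0.432 untreated, 0.543 at day 5 and 0.378 at day 7), so a block within each condition was added. Also added after seeing the data were fits without distal chromosome 5 and chromosome Y, without both day 5 replicate 1 arrays, without the 638 genes that followed the stroma list over the 8 treated arrays (r over 0.8), and with crossed replicate numbers.

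The procedure was tested on simulated data with the means and spread of the 12345 genes, of which 67 were changed by a log2 value of 0.5, 67 by 1 and 66 by 2. Of those changed by 0.5, 67.2% were recovered in the untreated comparison, 67.2% at day 5, 67.2% at day 7 and 97% in the mean of the conditions. The shares for a change of 1 were 95.5%, 92.5%, 94% and 98.5% in the same order, and 100% for a change of 2 in each. Unchanged genes called numbered 14, 6, 11 and 8. In a contrast with no changed genes, 1 gene was called. A raised list ranked 1 by camera and 0 of 25 other lists were called. The simulated noise was independent between genes and arrays, with the same spread in all groups. The simulation therefore cannot judge the preset correlation of camera, arrays that deviate together or groups of unequal spread. Other tools were data.table (version 1.17.8), statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.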

Results

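Gene expression was measured on 12 Affymetrix arrays in EML1 cells, a progenitor line made from bone marrow of male BDF1 mice with the retroviral vector LRARalpha403SN, which can be led towards the B lineage with IL7 and stromal cells. The cells carried either the empty lentiviral vector pWPI or the same vector with TEL-AML1, the fusion of the transcription factors ETV6 and RUNX1 found in B-cell precursor leukaemia of children. Each vector was profiled untreated and after 5 and 7 days with IL7 and FLT3L, 2 cytokines of early lymphoid growth, giving 6 groups of 2 arrays. The series asks which genes TEL-AML1 regulates in these cells before and after that treatment. Per the labels' culture protocol, B-cell differentiation meant plating 50000 EML1 cells on OP9 stromal cells in another medium and serum, with IL7 at 10 ng/ml and FLT3L at 80 ng/ml. The sample titles name only IL7 and FLT3L, and that the treated cells had been on OP9 is read from that protocol. If so, a comparison of day 5 or day 7 with untreated cells sets cytokines, stroma, medium and serum together against the maintenance culture.

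The median intensity of an array lay between 68.1 and 72.9, and the number of arrays, 2 a group, limits the precision of every value. Arrays of a group correlated at 0.981 to 0.997 across genes and arrays of different groups at 0.950 to 0.993. The first principal component held 36.6% of the variance and the second 31.5%. Because the labels do not say whether replicates were separate cultures, the p-values measure the spread between these arrays, which may be technical. Fold changes are on the log2(intensity + 16) scale, with the standard error after ±, and intensities are group means ± SD (n = 2 arrays). Adjusted p-values are from limma with Benjamini-Hochberg adjustment over 12345 genes. The fit uses 1 spread per gene for all groups. On the log2 scale, the median gap between replicates was 0.0688 (empty vector) and 0.0682 (TEL-AML1) in untreated cells. At day 5 and day 7 it was 0.134 and 0.13 with the empty vector and 0.102 and 0.0976 with TEL-AML1, a difference that the standard errors do not show.

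In untreated cells, TEL-AML1 arrays held far more transcript of several surface and metabolic genes. Cda, the cytidine deaminase of pyrimidine salvage, stood at 906 ± 93.2 against 63.7 ± 8.06 with the empty vector (log2 fold change 3.53 ± 0.17, adjusted p = 3.27e-06). Dctd, the deaminase of deoxycytidylate, differed by 2.14 ± 0.12 (adjusted p = 6.5e-06), the tetraspanin gene Cd81 by 2.79 ± 0.37 and Mpp1, a scaffold of the red cell membrane, by 2.58 ± 0.15. The serotonin transporter gene Slc6a4 (2.21 ± 0.27), the dehydrogenase gene Dhrs9 (2.18 ± 0.15), the selenoprotein gene Selenop (2.18 ± 0.25) and Itm2a (2.13 ± 0.19) were higher as well. In the other direction, carbonic anhydrase Car2, an early red cell enzyme, stood at 57.3 ± 1.66 against 659 ± 2.56 (-3.20 ± 0.24, adjusted p = 5.14e-05). Tox, a nuclear factor of T-cell development, stood at 99.5 ± 1.49 against 862 ± 60.6 (-2.92 ± 0.14, adjusted p = 3.27e-06). Aim2, a sensor of cytosolic DNA (-2.72 ± 0.14), the cadherin gene Cdh17 (-2.43 ± 0.22), the guidance receptor genes Neo1 (-2.27 ± 0.18) and Nrp1 (-2.02 ± 0.22) and the urea transporter gene Slc14a1 (-1.77 ± 0.082) were lower too, with adjusted p-values between 3.27e-06 and 0.000317.

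Of 23 mast cell, basophil and eosinophil genes, 7 were higher and none lower in untreated TEL-AML1 cells (11 and 0 adjusted over the list alone), with a median difference of 0.35 (camera adjusted p = 9.92e-08). The list's adjusted p was 0.216 with an estimated correlation. The tryptase gene Tpsab1 differed by 0.53 ± 0.086 (adjusted p = 0.00305). Hdc, which makes histamine, differed by 1.65 ± 0.34 and Ms4a2, a chain of the high-affinity IgE receptor, by 1.69 ± 0.33. Leaving out any 1 of the 4 untreated arrays of either vector raised the adjusted p of Hdc to as much as 0.0805 and that of Ms4a2 to as much as 0.0735.

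Adhesion and homing genes had 7 of 20 higher and 1 lower in the untreated TEL-AML1 arrays (8 and 2 adjusted over the list alone, camera adjusted p = 0.0176). With an estimated correlation its adjusted p was 0.216. Among them were the hyaluronan receptor gene Cd44 (1.67 ± 0.25) and the integrin genes Itgb2 (0.83 ± 0.074) and Itga6 (0.58 ± 0.076). A further integrin chain, Itgb4, was higher by 1.92 ± 0.14. Of 20 targets of p53, 6 were lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0186). An estimated correlation gave the list adjusted p = 0.683. The RNA-binding protein gene Zmat3 (-1.06 ± 0.17), the death gene Pmaip1 (-0.80 ± 0.12) and Mdm2, the ubiquitin ligase of p53 (-0.75 ± 0.11), were among the lower ones. Single genes of other lists included Gata1, the red cell and megakaryocyte factor (1.07 ± 0.19, adjusted p = 0.0048), the stem cell homeobox gene Meis1 (-1.09 ± 0.13), cyclin Ccnd2 (-0.98 ± 0.12), the cystine transporter gene Slc7a11 (-1.36 ± 0.21) and 2 genes of TGF-beta signalling, Smad3 (-0.89 ± 0.10) and Smurf1 (-0.95 ± 0.083), of which Smurf1 lies on distal chromosome 5. Sterol synthesis genes had a median difference of 0.21 with 1 of 19 higher (1 and 0 adjusted over the list alone, camera adjusted p = 0.00115). Its adjusted p became 0.683 with an estimated correlation. Immediate early genes had a median of 0.17 with 2 of 23 higher (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00547). For this list, an estimated correlation gave adjusted p = 0.683. Granulocyte genes had 2 of 17 higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.0327, adjusted p = 0.394 with an estimated correlation and 0.165 without a filter on dim genes).

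Altogether 1096 genes differed between the vectors in untreated cells, 337 higher and 759 lower with TEL-AML1, of which 55 and 78 changed by more than 2-fold. Both genes of the fusion have probe sets here. Etv6 differed by 0.32 ± 0.082 (adjusted p = 0.0349), a call that ended without any 1 of the 4 untreated arrays (adjusted p up to 0.241). Runx1 differed by 0.11 ± 0.11 (adjusted p = 0.713). Whether either probe set reads the human fusion transcript was not tested. Epor, a gene linked to the fusion, differed by 0.02 ± 0.12 (adjusted p = 0.986). The count was 493 without empty-vector replicate 1, 520 without replicate 2, 532 without TEL-AML1 replicate 1 and 476 without replicate 2. It was 2600 with array weights and 2369 when only the untreated groups were fitted. With each array centred on its median, 417 genes were higher and 507 lower.

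**Figure D1:**
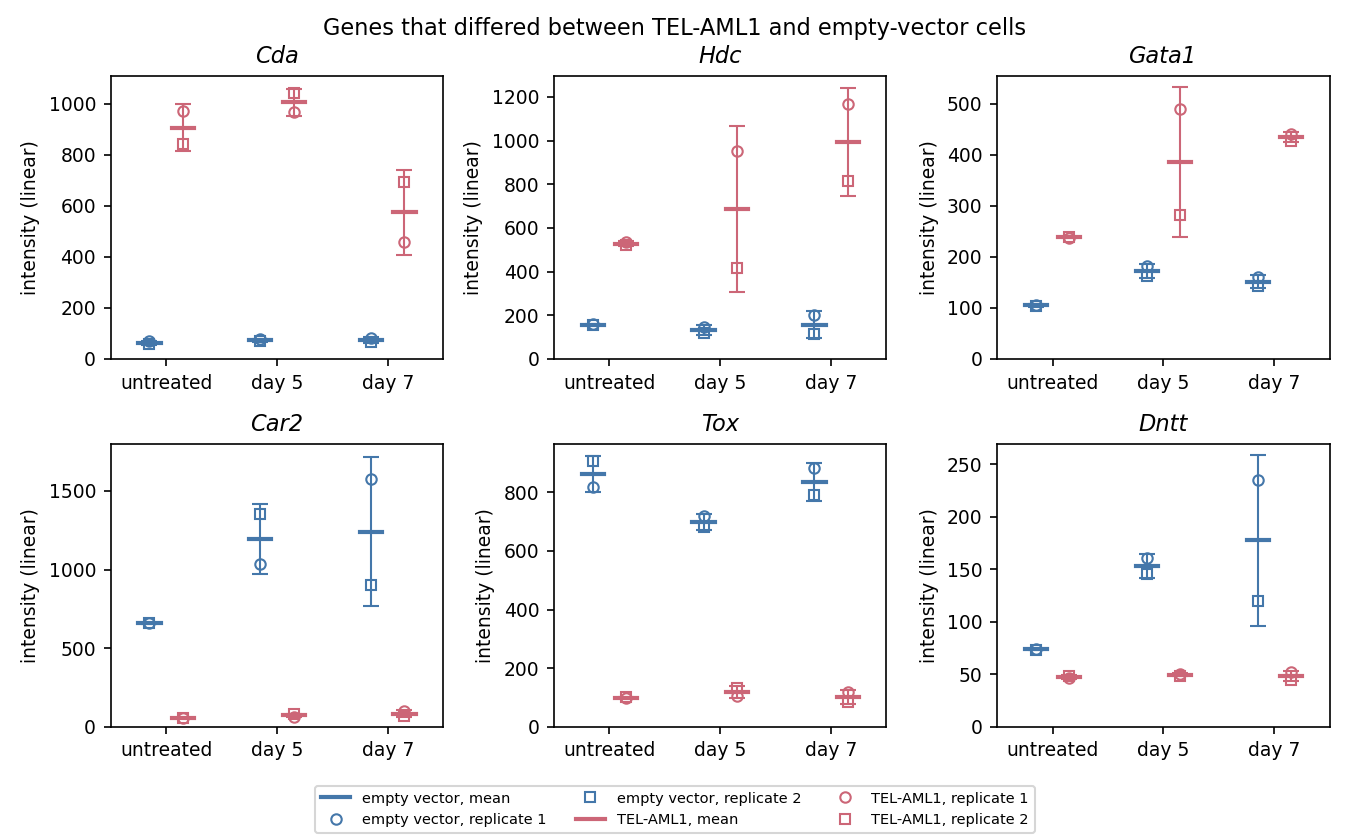
Intensity (linear scale) of 6 genes in empty-vector and TEL-AML1 cells, untreated and at day 5 and day 7, with 1 symbol per array, the mean as a bar and the SD of 2 arrays as whiskers. Cda, Hdc and Gata1 stand higher with TEL-AML1 in every condition plotted, and Car2, Tox and Dntt stand lower.

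On chromosome 5, in the gene order of GRCm38.p6, a distal stretch from Taok3 to Rfc3 was bounded by the TEL-AML1 differences themselves. It held 333 tested genes. In untreated cells 198 of them were called lower, 26.1% of all lower calls, and 3 higher. The 175 bright genes of that stretch had a median difference of -0.594 in untreated cells, -0.514 at day 5 and -0.551 at day 7, while the rest of the chromosome had medians of -0.046, 0.018 and 0.004. At day 5, 147 genes of the stretch were called lower (27.9% of lower calls) and 2 higher, and at day 7, 172 lower (23.2%) and 6 higher. Of 5 tested chromosome Y genes, 3 were higher in each condition and none lower. Eif2s3y, a translation factor gene, stood at 457 and 493 on the untreated TEL-AML1 arrays and at 178 and 194 on the empty-vector arrays, and the demethylase genes Uty (384 and 384 against 144 and 138) and Kdm5d (229 and 218 against 108 and 109) were higher too. Sry (113 and 105 against 112 and 97) and Sly did not pass in the mean of the conditions (0.01, adjusted p = 0.945, and -0.155, adjusted p = 0.555). Without distal chromosome 5 and chromosome Y, 825 genes differed in untreated cells, 684 at day 5 and 1142 at day 7.

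**Figure D2:**
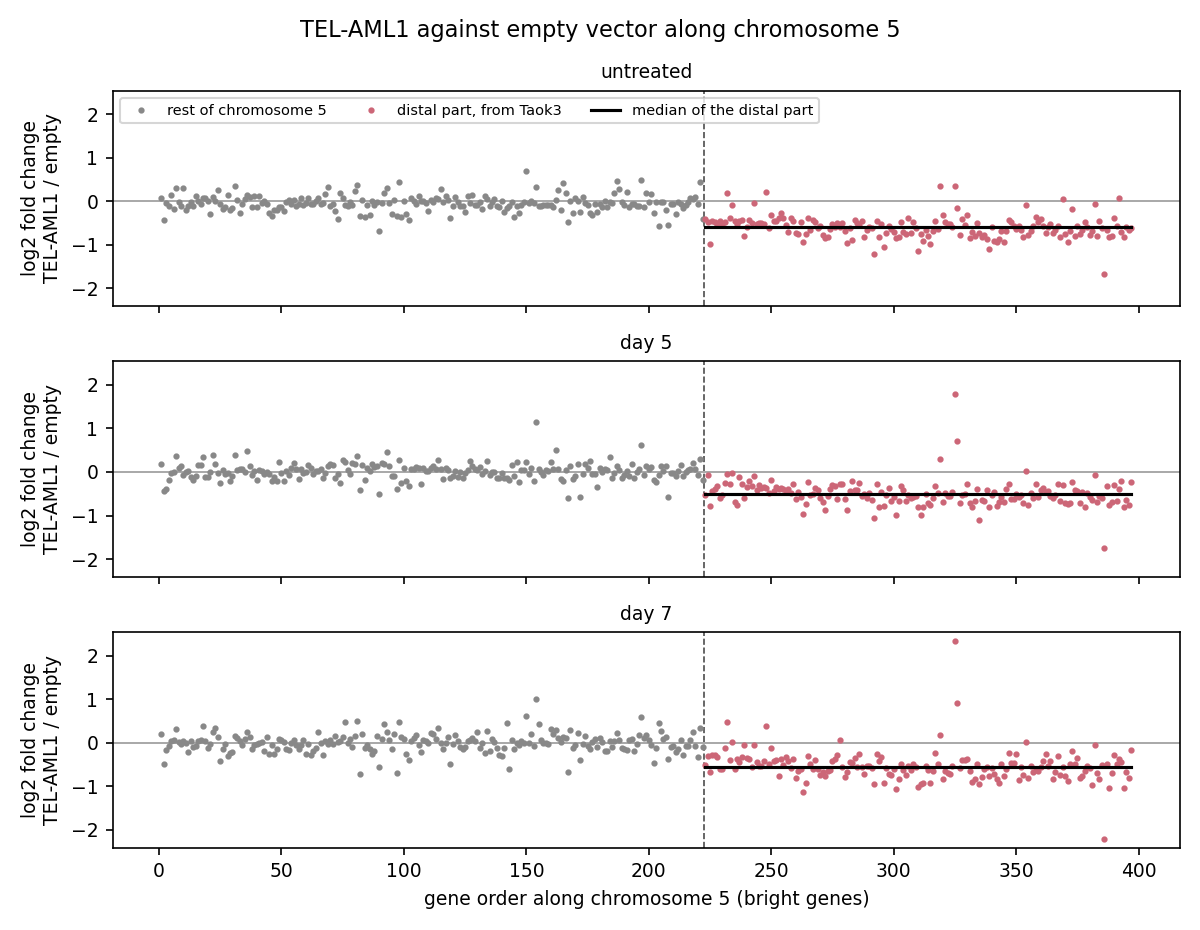
Log2 fold change of TEL-AML1 over empty vector for 397 bright genes of chromosome 5 in genomic order, in untreated cells and at day 5 and day 7 (2 arrays a group), with 1 point per gene. The 175 genes to the right of the dashed line lie around medians of -0.594, -0.514 and -0.551 (black lines), and genes to its left lie around 0.

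At day 5 of treatment, Cda again stood highest with TEL-AML1, at 1006 ± 53 against 73.5 ± 5.05 (3.51 ± 0.17, adjusted p = 1.33e-05). The tetraspanin gene Tspan13 (2.76 ± 0.21), the membrane protein gene Ms4a6c of the monocyte list (2.28 ± 0.19), Hdc (2.13 ± 0.34) and Gpr183, a receptor that guides lymphocytes (2.05 ± 0.11), were higher as well, with adjusted p-values between 1.33e-05 and 0.00392. Car2 stood at 72.6 ± 12.3 against 1195 ± 223 (-3.77 ± 0.24, adjusted p = 2.49e-05). Tox (-2.41 ± 0.14), Aim2 (-2.23 ± 0.14), the clotting factor gene F13a1 (-2.14 ± 0.12), Slc7a11 (-1.91 ± 0.21), the VEGF receptor gene Flt1 (-1.74 ± 0.17, on distal chromosome 5) and the chemokine receptor gene Ccr2 (-1.35 ± 0.10) were lower.

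By list, mast cell, basophil and eosinophil genes had 4 of 23 higher and none lower with TEL-AML1 at day 5 (7 and 1 adjusted over the list alone, camera adjusted p = 0.000287). This shift had adjusted p = 0.679 with an estimated correlation. Sterol synthesis genes had 5 of 19 higher, all 5 also when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 5.79e-06). Camera with an estimated correlation gave adjusted p = 0.729. Msmo1, an enzyme that demethylates sterols, differed by 0.85 ± 0.17 (adjusted p = 0.0116), which rose to as much as 0.0794 without empty-vector day 5 replicate 2 or either TEL-AML1 day 5 array. Targets of p53 had 2 of 20 lower (5 adjusted over the list alone, camera adjusted p = 0.000805). At an estimated correlation the list had adjusted p = 0.679. Genes of OP9 stroma, named in the protocol and not in the sample titles, had a median of -0.49 with 1 of 34 higher and none lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.000232). The list's adjusted p was 0.858 with an estimated correlation. Erythroid genes had 3 of 23 higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.0331). Once the correlation was estimated, its adjusted p was 0.858. With each array's mean over the stroma list as a covariate, the adjusted p was 0.065 for the p53 targets and 0.065 for the erythroid genes. With the replicate number as a block within each condition, TGF-beta and BMP genes (median -0.127, camera adjusted p = 0.0275, against 0.05 without the block) and retinoic acid genes (median -0.166, adjusted p = 0.0273, against 0.0601, and 0.0311 with the stroma covariate) also passed. Without the block, an estimated correlation gave these lists adjusted p = 0.729 and 0.679. Lymphoid priming genes passed by camera with the stroma covariate (median -0.156, adjusted p = 0.0311, against 0.109 without it). Within the interferon list the vectors parted by gene, with Parp14, a poly-ADP-ribose polymerase, higher (1.20 ± 0.12), and Tap1 (-0.67 ± 0.11) and Psmb9 (-0.63 ± 0.099), of antigen processing, lower. Etv6 (0.17 ± 0.082, adjusted p = 0.274) and Runx1 (0.05 ± 0.11, adjusted p = 0.852) did not pass the test.

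In total 900 genes differed at day 5, 373 higher and 527 lower with TEL-AML1 (48 and 52 by more than 2-fold). The count was 450 without empty-vector day 5 replicate 2, 574 without TEL-AML1 day 5 replicate 1 and 574 without its replicate 2, 369 without both day 5 replicate 1 arrays, and 325 when only the day 5 groups were fitted, which ended the calls of Msmo1, Tap1 and Psmb9 (adjusted p = 0.0737, 0.0517 and 0.0785). With the replicate number as a block within each condition it was 1827.

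At day 7, Tspan13 (3.12 ± 0.21, adjusted p = 2.22e-05) and Ms4a6c, at 530 ± 171 against 57.8 ± 12.8 (2.86 ± 0.19), were higher with TEL-AML1. Gpr183 (2.70 ± 0.11), Cda (2.68 ± 0.17), Hdc (2.57 ± 0.34) and Cmpk2, a mitochondrial nucleotide kinase induced by interferon (2.57 ± 0.27), were also higher. Car2 (-3.62 ± 0.24), Tox (-2.86 ± 0.14), the secreted protein gene Islr (-2.64 ± 0.19), Flt1 (-2.21 ± 0.17, on distal chromosome 5), F13a1 (-2.18 ± 0.12) and Slc7a11 (-2.15 ± 0.21) were lower, with adjusted p-values between 4.1e-06 and 0.000168. Dntt, the terminal transferase of early lymphoid cells, stood at 48.4 ± 5.03 against 177 ± 81.2 (-1.52 ± 0.21, adjusted p = 0.00125) and, at day 5, at 49.6 ± 1.61 against 153 ± 11.1 (-1.36 ± 0.21, adjusted p = 0.00346, and 0.0787 without both day 5 replicate 1 arrays).

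Mast cell, basophil and eosinophil genes had 9 of 23 higher and 1 lower at day 7 (10 and 1 adjusted over the list alone, median 0.41, camera adjusted p = 1.69e-07). An estimated correlation gave the list adjusted p = 0.364. Ms4a2 (2.55 ± 0.33), the chymase gene Cma1 (2.06 ± 0.30) and the cytokine receptor chain genes Csf2rb (0.81 ± 0.094) and Csf2rb2 (0.77 ± 0.091) were among them. Erythroid genes had 7 of 23 higher and 2 lower (11 and 3 adjusted over the list alone, camera adjusted p = 0.0024), the higher ones including carbonic anhydrase Car1 (2.98 ± 0.49), Gata1 (1.43 ± 0.19) and Nfe2, a factor of globin genes (0.86 ± 0.14), and the lower ones Car2. Its adjusted p became 0.821 with an estimated correlation. Interferon genes had 4 of 29 higher and none lower (4 and 1 adjusted over the list alone, median 0.27, camera adjusted p = 0.00257), among them Parp14 (1.85 ± 0.12) and the antiviral gene Rsad2 (1.56 ± 0.13). For this list, an estimated correlation gave adjusted p = 0.821. Cell cycle genes had 6 of 31 lower and none higher (8 and 0 adjusted over the list alone, camera adjusted p = 0.00463), among them cyclin Ccna2 (-0.45 ± 0.066). This shift had adjusted p = 0.821 with an estimated correlation and 0.0501 with the stroma covariate. Targets of p53 had 4 of 20 lower (5 adjusted over the list alone, camera adjusted p = 0.006), with Zmat3 at -1.13 ± 0.17. Camera with an estimated correlation gave adjusted p = 0.821. Sterol genes had 1 of 19 higher (1 adjusted over the list alone, camera adjusted p = 0.000809). At an estimated correlation the list had adjusted p = 0.821. Stroma genes had a median of -0.25 with 1 of 34 higher (camera adjusted p = 0.206), and with the block within each condition their adjusted p was 0.000723. Bach2, a B-cell repressor, was higher by 0.63 ± 0.086. Etv6 (0.12 ± 0.082, adjusted p = 0.421), Runx1 (0.07 ± 0.11, adjusted p = 0.728) and Epor (0.28 ± 0.12, adjusted p = 0.177) did not pass.

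In total 1389 genes differed at day 7, 648 higher and 741 lower with TEL-AML1 (86 and 59 by more than 2-fold). The count was 754 without TEL-AML1 day 7 replicate 1, 782 without its replicate 2, 899 with array weights, 367 when only the day 7 groups were fitted (which ended the calls of Car1, Dntt, Nfe2 and Ccna2), and 2207 with the block within each condition.

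Averaged over the 3 conditions, which sets 6 arrays against 6, the genes on the higher side included Cda (3.24 ± 0.098, adjusted p = 3.06e-08), Tspan13 (2.52 ± 0.12), Mpp1 (2.38 ± 0.086) and Gpr183 (2.10 ± 0.063). Car2 (-3.53 ± 0.14), Tox (-2.73 ± 0.079, adjusted p = 3.06e-08), Aim2 (-2.43 ± 0.079) and Slc43a3, a purine base transporter gene (-2.07 ± 0.056), were on the lower side. Of 23 mast cell, basophil and eosinophil genes, 16 were higher and 1 lower (17 and 1 adjusted over the list alone, camera adjusted p = 3.3e-08), with Hdc at 2.12 ± 0.20, Ms4a2 at 2.04 ± 0.19 and Cma1 at 1.47 ± 0.17. The list's adjusted p was 0.301 with an estimated correlation. Of 19 sterol synthesis genes, 12 were higher and none lower (15 and 1 adjusted over the list alone, camera adjusted p = 3.94e-06), with Msmo1 at 0.64 ± 0.096 and the synthase gene Hmgcs1 at 0.51 ± 0.096. Under an estimated correlation its adjusted p was 0.828. Of 20 targets of p53, 8 were lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.000779): Zmat3 stood at -1.06 ± 0.097 and Mdm2 at -0.64 ± 0.065, against 0.66 ± 0.098 for Perp, a desmosome gene. An estimated correlation gave the list adjusted p = 0.705. Erythroid genes went both ways, 9 higher and 3 lower of 23 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00708), with Gata1 at 1.18 ± 0.11 and Epb42, a red cell membrane gene, at -0.98 ± 0.077. Its adjusted p became 0.828 with an estimated correlation. The gene calls named for this mean held without any 1 of the 12 arrays and under each of the other settings tried. Genes were picked with preference for calls that held without each single array, so this is partly a result of the choice.

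The other lineage lists showed no shift in the mean over conditions by camera. The B lineage list had 1 higher and 5 lower of 21 (1 and 6 adjusted over the list alone, adjusted p = 0.336) with Bach2 at 0.46 ± 0.05 and Dntt at -1.13 ± 0.12. Lymphoid priming genes had 0 higher and 4 lower of 13 (0 and 5 adjusted over the list alone, adjusted p = 0.29). Stem and progenitor genes had 6 higher and 3 lower of 23 (6 and 3 adjusted over the list alone, adjusted p = 0.452), among them Meis1 (-0.72 ± 0.076), Angpt1, a ligand of the TIE2 receptor (1.12 ± 0.10), and Etv6 (0.20 ± 0.047, adjusted p = 0.0107). Megakaryocyte genes had 1 higher and 4 lower of 18 (1 and 4 adjusted over the list alone, adjusted p = 0.29), with the platelet glycoprotein gene Gp9 at -1.06 ± 0.057. Granulocyte genes had 5 higher and 1 lower of 17 (6 and 1 adjusted over the list alone, adjusted p = 0.29), and monocyte and macrophage genes 5 higher and 3 lower of 19 (5 and 4 adjusted over the list alone, adjusted p = 0.45). Dendritic cell and antigen presentation genes had 1 higher and 0 lower of 9 (1 and 0 adjusted over the list alone, adjusted p = 0.29). T and NK cell genes had 3 higher and 2 lower of 11 (3 and 2 adjusted over the list alone, adjusted p = 0.581), with Cd7, a T-cell surface gene, at 1.24 ± 0.071. Genes linked to RUNX1 had 5 higher and 5 lower of 22 (5 and 5 adjusted over the list alone, adjusted p = 0.731), with the protein kinase C gene Prkcq at 1.11 ± 0.05. Runx1 itself stood at 0.08 ± 0.061 (adjusted p = 0.435) and Epor at 0.17 ± 0.07 (adjusted p = 0.12, and 0.0344 with the block within each condition). Stroma genes had 2 higher and 2 lower of 34 (1 and 0 adjusted over the list alone, adjusted p = 0.0973). Their camera adjusted p was 4.67e-05 with the block within each condition and 0.0289 without a filter on dim genes (median -0.209). Adipocyte genes had 1 higher and 0 lower of 13 (1 and 0 adjusted over the list alone, adjusted p = 0.958).

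Among process lists in the same mean, cell cycle genes had 2 higher and 7 lower of 31 (2 and 9 adjusted over the list alone, adjusted p = 0.292). Apoptosis regulators had 1 higher and 2 lower of 20 (1 and 2 adjusted over the list alone, adjusted p = 0.82) and interferon genes 4 higher and 4 lower of 29 (4 and 5 adjusted over the list alone, adjusted p = 0.731). Targets of JAK and STAT signalling had 6 higher and 2 lower of 20 (6 and 2 adjusted over the list alone, adjusted p = 0.278), with the IL2 receptor gene Il2ra at 0.41 ± 0.048, the kinase gene Pim2 at 0.50 ± 0.079 and Ccnd2 at -0.57 ± 0.068. The TGF-beta and BMP list had 1 higher and 4 lower of 22 (1 and 5 adjusted over the list alone, adjusted p = 0.29) and the retinoic acid list 1 higher and 3 lower of 9 (1 and 4 adjusted over the list alone, adjusted p = 0.29). Immediate early genes had 3 higher and 0 lower of 23 (3 and 0 adjusted over the list alone, adjusted p = 0.581), and hypoxia and glycolysis genes 5 higher and 3 lower of 25 (6 and 3 adjusted over the list alone, adjusted p = 0.706). Genes of ER stress and the integrated stress response had 2 higher and 2 lower of 25 (2 and 2 adjusted over the list alone, adjusted p = 0.749). Adhesion and homing genes had 7 higher and 4 lower of 20 (7 and 4 adjusted over the list alone, adjusted p = 0.278). Median, mean and test differed in sign for the adhesion, adipocyte, apoptosis, ER stress, hypoxia, immediate early, RUNX1-linked, stem and T and NK lists of this comparison. By fry, the megakaryocyte (adjusted p = 0.0363), TGF-beta and BMP (0.023) and retinoic acid lists (0.0363) passed downwards in this mean. The granulocyte (0.0477), JAK-STAT (0.0363), RUNX1-linked (0.023) and adhesion lists (0.00151) passed upwards. Of the lists called by camera, the mast cell (0.00138), sterol (0.0363) and p53 lists (0.00263) passed by fry and the erythroid list (0.233) did not. In total 2786 genes differed in the mean, 1213 higher and 1573 lower (57 and 57 by more than 2-fold), and with each array centred on its median 1408 were higher and 1282 lower. By the single conditions, 175 were called higher and 335 lower in each of the 3 conditions.

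Treatment of empty-vector cells brought large rises in interferon-induced genes. Usp18, which limits interferon signalling, went from 90.8 ± 2.26 to 1435 ± 406 at day 5 (3.74 ± 0.21, adjusted p = 6.07e-06) and 1431 ± 321 at day 7 (3.74 ± 0.21). Ifitm3 (4.41 ± 0.40 and 3.56 ± 0.40), Ifit1 (3.42 ± 0.20 and 3.24 ± 0.20) and Oasl2 (3.24 ± 0.17 and 3.21 ± 0.17), all antiviral effector genes, rose on both days, as did Rtp4 (3.03 ± 0.14 and 3.09 ± 0.14), Irf7, a transcription factor of the interferon response (2.81 ± 0.097 and 2.67 ± 0.097), and Trim30a (2.78 ± 0.10 and 2.71 ± 0.10). Of 29 interferon genes, 25 rose at day 5 (28 adjusted over the list alone, median 1.14, camera adjusted p = 8.36e-33) and 23 at day 7 (25 adjusted over the list alone, median 1.10, camera adjusted p = 4.03e-26). With an estimated correlation the adjusted p was 0.0475 at day 5 and 0.0843 at day 7. Ifitm3 also followed the stroma genes over the 8 treated arrays (r = 0.918).

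In the same cells at day 5, the matrix genes Fn1, from 57.6 ± 1.73 to 1912 ± 476 (4.69 ± 0.82, adjusted p = 0.00754), and Bgn (3.86 ± 0.65), and the chemokine gene Cxcl12 (3.26 ± 0.67) were among 29 of 34 OP9 stroma genes that rose (31 adjusted over the list alone, median 1.20, camera adjusted p = 1.51e-18). For this list, an estimated correlation gave adjusted p = 0.408. The adjusted p reached 0.0704 for Fn1 without an untreated empty-vector array (replicate 1 or 2), 0.0628 for Bgn without replicate 2 of them, and 0.0981 for Cxcl12 without either of them or day 5 replicate 1. At day 7, 2 of 34 rose (0 adjusted over the list alone, median 0.47, camera adjusted p = 3.15e-05). This shift had adjusted p = 0.582 with an estimated correlation. Replicates differed in this list, whose mean log2 value was 8.28 and 7.89 on the day 5 arrays, 6.85 and 7.65 on the day 7 arrays and 6.56 and 6.50 on the untreated arrays of the empty vector. Adipocyte genes (6 of 13 up and 2 down at day 5, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0207) and TGF-beta and BMP genes (5 of 22 up, 6 adjusted over the list alone, camera adjusted p = 0.0207) lost their shift when the stroma list entered the fit as a covariate (adjusted p = 0.863 for each). Under an estimated correlation these adjusted p-values were 0.408 and 0.463.

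**Figure D3:**
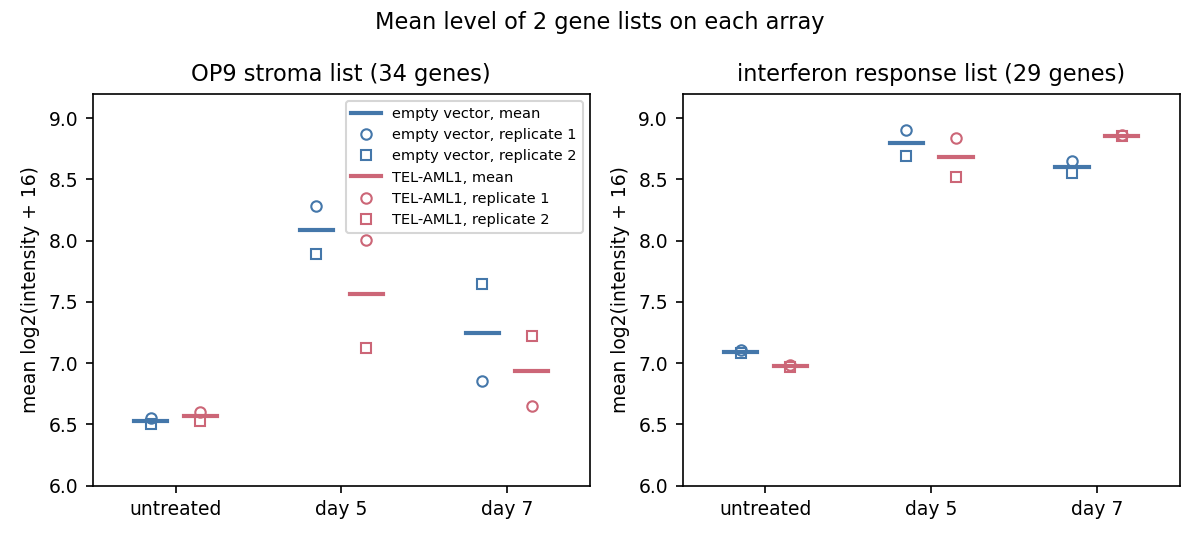
Mean log2(intensity + 16) of 34 OP9 stroma genes (left) and 29 interferon response genes (right) on each of the 12 arrays, by vector and condition, with 1 symbol per array and the group mean as a bar. On the treated arrays stroma means run from 6.65 to 8.28 and differ between replicates, while interferon means run from 8.52 to 8.90, above the 6.97 to 7.11 of untreated arrays.

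Of 25 genes of ER stress and the integrated stress response, 11 fell at day 5 in empty-vector cells (12 down and 1 up adjusted over the list alone, camera adjusted p = 1.66e-05) and 12 at day 7 (13 adjusted over the list alone, camera adjusted p = 1.25e-05). The respective adjusted p-values were 0.408 and 0.582 with an estimated correlation. Chac1, a glutathione-degrading enzyme induced by ATF4, stood at -1.40 ± 0.11 and -1.77 ± 0.11 at day 5 and day 7, and Mthfd2, of mitochondrial folate metabolism, at -0.99 ± 0.093 and -1.16 ± 0.093. The transaminase gene Gpt2 (-1.28 ± 0.10) fell at day 5, and the glycolytic gene Pfkp (-1.18 ± 0.12) and the Golgi kinase gene Gask1b (-2.21 ± 0.30) at day 7. Ccr2, the receptor that draws monocytes from marrow, rose from 144 ± 6.87 to 938 ± 53.2 and 733 ± 9.77 (2.57 ± 0.10 and 2.23 ± 0.10). Angpt1 rose at day 5 (1.33 ± 0.18) and the survival gene Bcl2 at day 7 (0.68 ± 0.091, ended when only the compared groups were fitted). Cell cycle genes had 4 of 31 down at day 5 (8 adjusted over the list alone, camera adjusted p = 0.000102) and 5 at day 7 (9 adjusted over the list alone, camera adjusted p = 8.78e-05). An estimated correlation gave adjusted p-values of 0.505 and 0.582 in that order.

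In the empty vector 1920 genes changed by day 5, 1037 up and 883 down (229 and 22 by more than 2-fold), and 1907 by day 7, 774 up and 1133 down (81 and 39). The day 5 count was 369 without untreated replicate 1, 202 without untreated replicate 2, 943 without day 5 replicate 2, 426 with the stroma covariate and 1403 without 638 genes that followed the stroma list. The day 7 count was 445 and 303 without untreated replicate 1 or 2, 622 without day 7 replicate 1, and 295 when only the compared groups were fitted.

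Interferon-induced genes also rose in TEL-AML1 cells after treatment. Usp18 went from 78.3 ± 3.44 to 1586 ± 291 and 1790 ± 317 (4.08 ± 0.21 at day 5 and 4.25 ± 0.21 at day 7, adjusted p = 3.2e-06 and 1.65e-06). Ifitm3 (4.02 ± 0.40 and 3.48 ± 0.40), Oasl2 (3.74 ± 0.17 and 4.22 ± 0.17), Rtp4 (3.23 ± 0.14 and 3.67 ± 0.14), Irf7 (3.02 ± 0.097 and 3.22 ± 0.097) and Trim30a (2.70 ± 0.10 and 3.04 ± 0.10) rose on both days. Of 29 interferon genes, 21 rose at day 5 (28 adjusted over the list alone, median 1.41, camera adjusted p = 1.09e-50) and 24 at day 7 (27 adjusted over the list alone, median 1.60, camera adjusted p = 1.98e-40). In the same order, an estimated correlation gave adjusted p = 0.015 and 0.0275. Ms4a6c rose by 1.80 ± 0.19 at day 5 and 2.52 ± 0.19 at day 7, and Ccr2 by 1.22 ± 0.10 at day 7. Dhrs9 fell (-1.34 ± 0.15 and -1.79 ± 0.15), as did Chac1 (-1.67 ± 0.11 and -1.85 ± 0.11) and Mthfd2 (-0.77 ± 0.093 and -1.31 ± 0.093, with adjusted p = 0.0504 at day 5 under the stroma covariate).

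Of 31 cell cycle genes, 16 fell by day 7 in TEL-AML1 cells (20 adjusted over the list alone, median -0.37, camera adjusted p = 1.77e-12), with the checkpoint kinase gene Bub1 at -0.68 ± 0.10 and the spindle gene Tpx2 at -0.60 ± 0.077. Camera with an estimated correlation gave adjusted p = 0.206. At day 5 none of the 31 passed, also when adjusted over the list alone (camera adjusted p = 3.84e-05). At an estimated correlation the list had adjusted p = 0.42. Of 23 erythroid genes, 8 rose at day 7 (14 up and 1 down adjusted over the list alone, camera adjusted p = 2.44e-06) and 1 at day 5 (7 adjusted over the list alone, camera adjusted p = 0.000118). With an estimated correlation these adjusted p-values were 0.334 and 0.42. Nfe2 stood at 0.94 ± 0.14 at day 7 and Car1 at 3.07 ± 0.49, whose adjusted p of 0.00503 became 0.0533 without untreated TEL-AML1 replicate 1. Of 25 stress response genes, 4 fell at day 5 (8 adjusted over the list alone, camera adjusted p = 8.11e-09) and 10 at day 7 (13 adjusted over the list alone, camera adjusted p = 2.13e-09). The respective adjusted p-values were 0.378 and 0.206 with an estimated correlation. Stroma genes had a median of 0.70 at day 5 with none of 34 passing (26 up adjusted over the list alone, camera adjusted p = 2.11e-13) and of 0.20 at day 7 (1 up, 1 adjusted over the list alone, camera adjusted p = 0.0347). An estimated correlation gave adjusted p-values of 0.42 and 0.738 in that order. Fn1 went from 60.4 ± 1.13 to 1235 ± 954 at day 5 (3.79 ± 0.82, adjusted p = 0.0541, 0.0397 with the filter at the 60th percentile and 0.00962 with array weights), and the stroma list's mean intensity was 385 and 208 on the day 5 arrays and 164 and 235 on the day 7 arrays.

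In TEL-AML1 cells 197 genes changed by day 5, 144 up and 53 down (61 and 6 by more than 2-fold), and 964 by day 7, 585 up and 379 down (95 and 17). The day 5 split was 104 up and 74 down with each array centred on its median. The count was 79 without untreated replicate 1, 85 without untreated replicate 2, and 88 without day 5 replicate 1. It was 86 without both day 5 replicate 1 arrays, 84 with the stroma covariate and 468 with array weights. Removing an array of another group moved it too, to 131 without either untreated empty-vector array and 319 without either day 7 empty-vector array. The day 7 split was 383 up and 598 down after centring and 502 up and 502 down after quantile normalization. The day 7 count was 218 and 199 without untreated replicate 1 or 2, 295 and 508 without day 7 replicate 1 or 2, and 599 without either untreated and 1495 without either day 7 empty-vector array. It was 2233 with array weights, 1461 with the stroma covariate and 1637 with only the compared groups.

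The B lineage list showed no shift by camera in any of the 12 comparisons. In empty-vector cells at day 5, 3 of its 21 tested genes rose (3 adjusted over the list alone, camera adjusted p = 0.314), namely Ebf1, a B-lineage factor also made by stromal and fat precursor cells (1.93 ± 0.43), the actin-binding gene Cnn3 (1.91 ± 0.39) and Dntt (0.91 ± 0.21). Ebf1 and Cnn3 followed the stroma list over the 8 treated arrays, and with that list as a covariate their values were -0.246 and -0.042. These 3 calls ended without either untreated empty-vector array or day 5 replicate 1, and that of Dntt also without day 5 replicate 2 (adjusted p up to 0.118, 0.107 and 0.126). In TEL-AML1 cells Ebf1 stood at 1.14 ± 0.43 at day 5 (adjusted p = 0.254) and Dntt at 0.04 ± 0.21 (adjusted p = 0.965). Another 15 genes of the list lay under the filter, among them Cd79a, with group means of 41.2 to 46.9, and Ms4a1, with 42.8 to 45.9. Without the filter, 1 of the 15 was called in TEL-AML1 cells at day 7 and none in the other treated-against-untreated comparisons.

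Between day 5 and day 7 no gene passed the test in either vector by limma, with 794 genes at an unadjusted p under 0.05 in empty-vector and 989 in TEL-AML1 cells, where 617 are expected by chance. Stroma genes had a median of -0.80 in empty-vector cells (0 of 34 called, 22 down adjusted over the list alone, camera adjusted p = 3.7e-24) and of -0.56 in TEL-AML1 cells (0 called, 0 adjusted over the list alone, camera adjusted p = 4.98e-10). In the same order, an estimated correlation gave adjusted p = 0.929 and 0.402. In TEL-AML1 cells cell cycle genes had a median of -0.26 (0 of 31 called, 8 down adjusted over the list alone, camera adjusted p = 1.33e-11) and mast cell, basophil and eosinophil genes of 0.25 (0 of 23 called, 1 up adjusted over the list alone, camera adjusted p = 3.64e-07). Under an estimated correlation these adjusted p-values were 0.279 and 0.26. Interferon genes had a median of -0.12 in empty-vector cells (camera adjusted p = 0.00126) and of 0.19 in TEL-AML1 cells (camera adjusted p = 6.27e-06). The respective adjusted p-values were 0.929 and 0.323 with an estimated correlation, and with the stroma covariate the empty-vector list had a median of -0.053 and adjusted p = 0.477. The count of 0 became 70 in empty-vector cells without day 7 replicate 2. In TEL-AML1 cells it became 17 without day 7 replicate 2, 4 without either day 7 empty-vector array and 1 with a pseudocount of 64.

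The response to treatment was compared between the vectors directly, as the difference of the 2 changes. At day 5, Ccr2 rose less with TEL-AML1 (-1.85 ± 0.14, adjusted p = 0.00119), a call kept without any 1 array and lost without both day 5 replicate 1 arrays. Dhrs9, highest in untreated TEL-AML1 cells among the 6 groups, had a difference of -2.09 ± 0.22 (adjusted p = 0.0113), Slc14a1 of 0.97 ± 0.12 (adjusted p = 0.0263) and Slfn5, an interferon-induced gene, of 0.78 ± 0.097 (adjusted p = 0.028). These were the 4 genes called at day 5. At day 7, 10 genes were called, among them Ms4a6c (2.35 ± 0.27), its family member Ms4a6b (2.23 ± 0.28), Parp14 (1.51 ± 0.17), Rsad2 (1.39 ± 0.19), Gpr183 (1.16 ± 0.15), Slc14a1 (1.12 ± 0.12) and Slfn5 (1.01 ± 0.097) with the larger rise in TEL-AML1 cells. Dhrs9 (-1.97 ± 0.22), the ubiquitin ligase gene Mid1 (-1.15 ± 0.16) and Ccr2 (-1.01 ± 0.14) differed the other way, and the 10 adjusted p-values lay between 0.0103 and 0.0331. With the replicate number as a block over all arrays, the adjusted p was 0.056 for Slfn5 at day 5 and 0.0556 for Gpr183, Mid1 and Ccr2 at day 7. Median centring gave 0.1 for Slc14a1 and 0.122 for Slfn5 at day 5, and 0.077 for Rsad2 and 0.0618 for Gpr183 at day 7. The call of Rsad2 also ended with quantile normalization (adjusted p = 0.0504) and that of Slfn5 at day 5 with the trended robust variance (0.0506). Without a filter, those of Ms4a6b, Rsad2, Gpr183, Mid1 and Ccr2 at day 7 ended (0.058 to 0.06). With only the compared groups, or without both day 5 replicate 1 arrays, the day 7 calls other than Slc14a1, Slfn5 and Dhrs9 ended (0.0586 to 0.08).

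By list, at day 5 the difference was negative for stroma genes (median -0.55, 0 of 34 called, camera adjusted p = 5.72e-08) and immediate early genes (median -0.36, 0 of 23 called, 1 up and 3 down adjusted over the list alone, camera adjusted p = 1e-04). At day 7 it was positive for interferon (median 0.30, 2 of 29 called, 4 adjusted over the list alone, camera adjusted p = 8.61e-07) and erythroid genes (median 0.26, adjusted p = 0.0063). It was negative for stroma (-0.31, adjusted p = 0.0063), cell cycle (-0.14, adjusted p = 0.00245, 1 down adjusted over the list alone) and immediate early genes (-0.35, adjusted p = 0.00547). With an estimated correlation these adjusted p-values lay between 0.801 and 0.927, and with the stroma covariate that of cell cycle genes at day 7 was 0.0611. The stroma list itself, whose shift this covariate removes by construction, then had medians of -0.032 at day 5 and -0.013 at day 7. That covariate also brought calls at day 5, for cell cycle (median 0.167, adjusted p = 0.0415), sterol synthesis (0.345, 0.0208), stem and progenitor (-0.132, 0.0316) and retinoic acid genes (-0.179, 0.0378). Without it these lists had adjusted p = 0.358, 0.194, 0.0733 and 0.111, and 0.868, 0.868, 0.808 and 0.801 with an estimated correlation. The gene counts of 4 and 10 had 946 and 1112 genes at an unadjusted p under 0.05. At day 5 the count was 1 without any of the 4 untreated arrays or TEL-AML1 day 5 replicate 1, 2 without either day 5 replicate 2 array, 19 without either day 7 empty-vector array, 2 with median centring and 0 without both day 5 replicate 1 arrays (adjusted p = 0.0966 to 0.195 for the 4 genes). It was 7 with array weights, 22 over every probe set, 9 with the stroma covariate, 16 with only the compared groups and 9 with the block within each condition. At day 7 it was 0 without any of the 4 untreated arrays, 4 without either day 5 empty-vector array, 19 and 74 without day 7 empty-vector replicate 1 or 2, and 23 without TEL-AML1 day 7 replicate 2. It was 5 without a filter, 21 with the stroma covariate, 3 with only the compared groups, 3 without both day 5 replicate 1 arrays and 32 with the block within each condition.

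**Figure D4:**
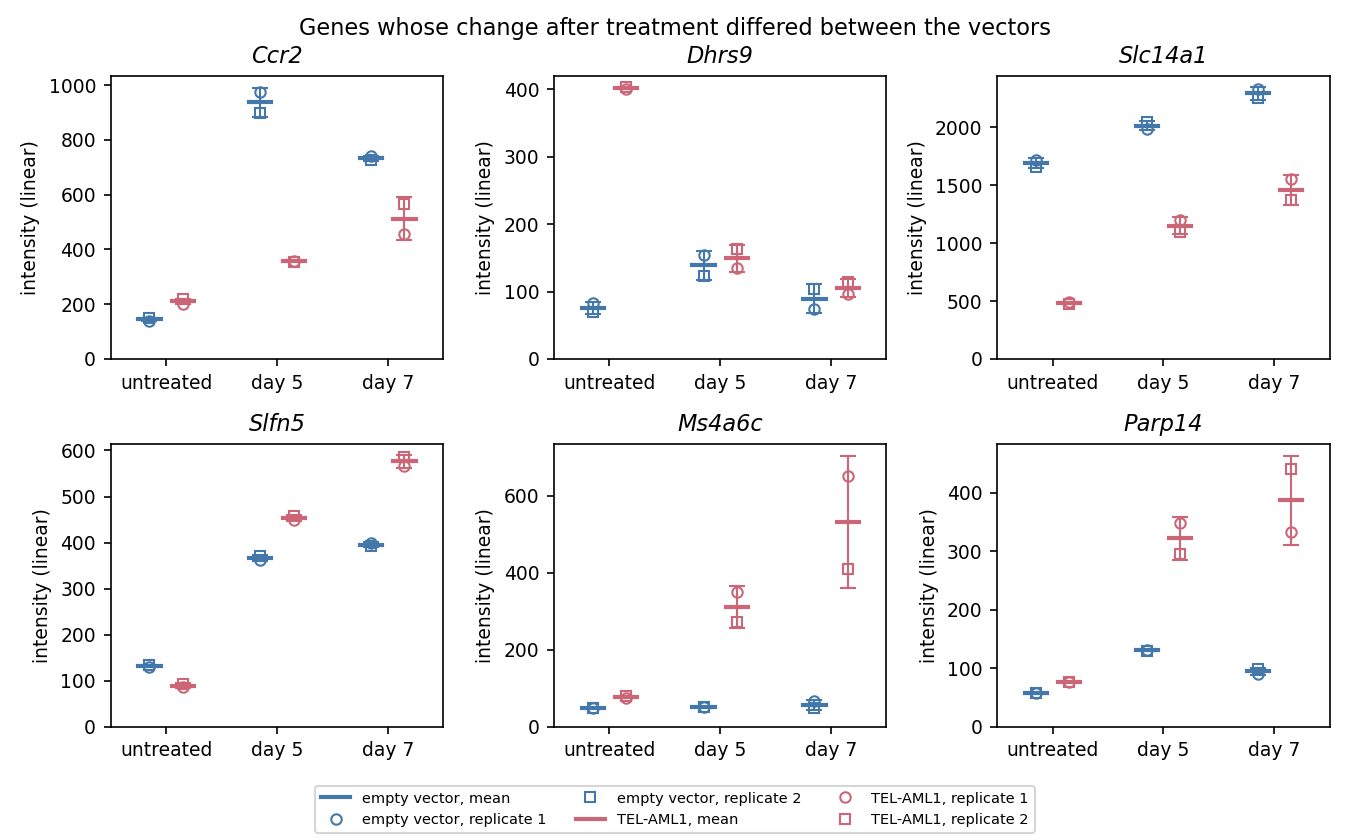
Intensity (linear scale) of 6 genes called in the comparison of the vectors' responses, in untreated, day 5 and day 7 cells, with 1 symbol per array, the group mean as a bar and the SD of 2 arrays as whiskers. Ccr2 climbs from 144 to 938 with the empty vector and from 210 to 357 with TEL-AML1 by day 5, and Ms4a6c stands at 530.5 with TEL-AML1 at day 7 against 57.8.

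Over 12345 genes, which are not independent replicates, the changes in empty-vector and TEL-AML1 cells correlated at r = 0.776 at day 5 and 0.71 at day 7 (Spearman rho = 0.556 and 0.61), from groups that share no array. These values include the 638 genes that followed the stroma list. Same-numbered arrays of the vectors also deviated together (r = 0.543 at day 5 and 0.378 at day 7). The agreement need not be a response of the EML1 cells alone. The sign was the same for 65.9% of all genes at day 5 and 69.1% at day 7. Of 1920 genes called in the empty vector at day 5, 94.1% had the same sign with TEL-AML1. In both vectors 116 were called higher and 40 lower, where independent lists would share 12.1 and 3.79. At day 7, 299 were called higher and 226 lower in both, against 36.7 and 34.8 for independent lists. The TEL-AML1 difference in untreated cells correlated with that at day 5 at r = 0.659 and with that at day 7 at 0.678, and the differences at day 5 and day 7 at 0.841 (rho = 0.404, 0.432 and 0.727). Of the genes called at day 5 and day 7, 284 were higher and 416 lower in both, against 19.6 and 31.6 for independent lists. All these lists come from 1 fit with 1 spread per gene, so they are not independent even where they share no array.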

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

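The tests of stromal RNA, of the interferon genes and of distal chromosome 5 were chosen after those results were seen, and the count over other splits of the arrays was chosen beforehand.

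Treatment changed some genes differently in the 2 vectors, by the test of the difference itself. At day 5 these were Ccr2 (-1.85, adjusted p = 0.00119), Dhrs9 (-2.09, adjusted p = 0.0113), Slc14a1 (0.97, adjusted p = 0.0263) and Slfn5 (0.78, adjusted p = 0.028). At day 7 they were Slc14a1 (1.12, adjusted p = 0.0103), Slfn5 (1.01, adjusted p = 0.0103), Dhrs9 (-1.97, adjusted p = 0.0126), Ms4a6c (2.35, adjusted p = 0.0126) and Parp14 (1.51, adjusted p = 0.0126). The others of day 7 were Ms4a6b (2.23, adjusted p = 0.0245), Gpr183 (1.16, adjusted p = 0.0293), Mid1 (-1.15, adjusted p = 0.0315), Rsad2 (1.39, adjusted p = 0.0315) and Ccr2 (-1.01, adjusted p = 0.0331). Each of these calls but that of Ccr2 at day 5 ended without any 1 of the 4 untreated arrays, and that of Ccr2 at day 5 ended without both day 5 replicate 1 arrays (adjusted p = 0.0966).

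Lists that differed between the responses by camera were OP9 stroma (-0.553, adjusted p = 5.72e-08) and immediate early genes (-0.361, adjusted p = 1e-04) at day 5. At day 7 they were erythroid genes (0.255, adjusted p = 0.0063), OP9 stroma (-0.309, adjusted p = 0.0063), cell cycle (-0.137, adjusted p = 0.00245), interferon (0.305, adjusted p = 8.61e-07) and immediate early genes (-0.354, adjusted p = 0.00547). With an estimated correlation the adjusted p-values of these lists were 0.801 to 0.927. The stroma list's mean excess in intensity over untreated arrays differed between replicates. At day 5 it was 315 and 204 with the empty vector and 241 and 63.4 with TEL-AML1. At day 7 it was 32.1 and 150, and 18.8 and 90. Probe sets left out of the gene comparisons also carried signal in the mean TEL-AML1 contrast. Of 1109 with several genes, 109 were called (49 higher and 60 lower), and of 6276 with no listed gene, 234 were called (146 higher and 88 lower).

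Stroma genes and Ebf1 rose together in the empty vector by day 5, with Fn1 going from 57.6 to 1912, Bgn from 61.28 to 1116 and Ebf1 from 48.9 to 236, while Igfbp4 (1633 and 1753) and Pdgfrb (904.1 and 938.4) of the same list were bright before; of its 34 genes, 18 lay above the filter on all untreated arrays and 1 is in another list. RNA of the OP9 cells would make the genes' excess over untreated arrays go up and down together over the 8 treated arrays. The median Pearson r of a gene with the mean of the others was 0.974 (over 0.8 for 31 of 34, lowest -0.556), against -0.117 for 29 interferon genes with the stroma mean, 3 of them over 0.8. Ebf1 followed the list's excess over the 8 treated arrays (Pearson r = 0.992, Spearman rho = 1), also without the 2 arrays farthest out (r = 0.991). Ebf1 was already among the 638 of 12345 genes found to follow the list on these arrays, so these values describe the relation and do not test it. The fitted Ebf1 excess at 0 stroma excess was -18.6 ± 6.84 (SE) against a mean of 89.5. A value below 0 shows that the straight line fails near 0 stroma, so no conclusion is drawn from it. On the day 7 replicate 1 arrays, stroma excess was 32.1 (empty vector) and 18.8 (TEL-AML1), and Ebf1 excess was 11.9 and 0.836. Ebf1 thus rose little on these arrays, but untreated Ebf1 lay under the filter limit of 59.9, where a small rise in the EML1 cells could be missed. Stromal RNA is a candidate explanation, the labels name OP9 cells only in the protocol and no step that removes them, and a response of the EML1 cells in proportion to the stroma around them was not tested.

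Interferon genes rose on the treated arrays of both vectors, by medians of 1.14 and 1.10 in the empty vector and 1.41 and 1.60 in TEL-AML1 cells at day 5 and day 7. Against stromal RNA as their source, the replicate 1 arrays fell to 0.102 (empty vector) and 0.078 (TEL-AML1) of their day 5 stroma excess by day 7, and kept 0.858 and 1.07 of their interferon excess, ratios 8.41 and 13.7 times as high. The replicate 2 arrays alone decide nothing, since their stroma excess changed little (ratios of 0.735 and 1.42, against 0.888 and 1.38 for interferon), but over all 8 treated arrays the interferon excess at 0 stroma excess was 412 ± 35.7 (SE), where its mean was 431. A lasting response to the lentiviral vector would stand as high in untreated cells, which carry it too, and is opposed by the smallest of the medians, 1.1. A response of the EML1 cells to the cytokines, the stromal contact, the medium or the serum, which by the protocol changed together, stays open and untested.

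Genes of distal chromosome 5 were lower in TEL-AML1 cells, with a median of -0.552 over the conditions and 170 of 175 bright genes lower. Stromal RNA is argued against by the median of -0.594 in untreated arrays, and the authors' normalization by the medians of the other autosomes in the 3 conditions, of which the farthest from 0 was -0.034. A copy number difference between the cultures is a candidate explanation, since 2 copies against 3 give a log2 ratio of -0.585, which lay between the quartiles of these genes in each condition. In 213 windows of up to 25 neighbouring bright genes, each of the 7 distal ones shifted by at least 0.346 in every condition. The window across the start of the stretch (Mvk to Wsb2) was counted elsewhere. Because that start was set from these same differences, the medians, quartiles and windows of the stretch describe it and are not independent support. Of windows elsewhere that kept 1 direction, the smallest shift of the 3 conditions was at most 0.0892. In single conditions windows elsewhere reached 0.171 (untreated), 0.169 (day 5) and 0.218 (day 7), those of both days on chromosome 15. The day 7 value lay above 0.173, which is 50% of the smallest distal shift, so the windows leave the explanation open. The chromosome 15 windows were positive on both days and of either sign in untreated cells. The chromosome 15 median stood at 0.143 on day 7 replicate 1 of TEL-AML1 and at 0.02 on its replicate 2, relative to the mean of all arrays. No DNA was measured, and an effect of TEL-AML1 on the region stays open and untested.

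Whether other groupings of the arrays give as many calls was asked with balanced splits of the 12 arrays. Of 100 splits drawn from 108, only 1, the real one, reached 2786 genes in the mean TEL-AML1 contrast, and the highest other gave 333. The calls thus followed the vectors more than any other drawn grouping of these arrays. That share cannot exclude chance differences between cultures. The real split keeps the arrays of each group on the same side, and the labels do not say whether these were separate cultures. If replicates were technical, any difference between the cultures that carry the vectors could rank the real split highest. Of the 31 drawn splits that part all 6 same-numbered pairs, the highest other also gave 333, and 84 of all those drawn gave 0.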

How the results depend on the processing

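The block within each condition, the crossed numbers, and the fits without distal chromosome 5 and chromosome Y, without both day 5 replicate 1 arrays and without genes that follow the stroma list were chosen after the data were seen. The limits are those of 2 arrays a group: without 1 array the lone array of its group is assumed to vary like the others, and 52 counts then moved by more than 1.5 times while 92 did not. Over the arrays left out, calls ranged from 476 to 1338 for TEL-AML1 against empty vector in untreated cells, 450 to 1172 at day 5, 754 to 1729 at day 7 and 1989 to 3271 in the mean. They ranged from 202 to 2445 for day 5 and 303 to 2797 for day 7 against untreated in the empty vector, 0 to 70 for day 7 against day 5, and in TEL-AML1 cells 79 to 319, 199 to 1495 and 0 to 17. For the difference between responses they ranged from 1 to 19 at day 5 and 0 to 74 at day 7. Over these fits, calls of named genes were kept 2698 times, lost 362 times and gained 6 times, and none changed sign. The counts moved both ways. An array left alone in its group adds nothing to the pooled spread. In comparisons without that group only this spread and its degrees of freedom changed, so leaving out either array of the group gave the same count. In comparisons with that group the differences changed too, and these causes were not separated. Named genes had been picked with preference for calls that held without each single array, so the kept calls are not independent support.

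The replicate number as a block (pairing) over all 12 arrays moved none of the 12 counts by over 1.5 times. It ended 8 named gene calls and kept 247. For the pairs within a condition, the block gave 1827 calls for TEL-AML1 against empty vector at day 5, 2207 at day 7, 9 for the response difference at day 5 and 32 at day 7; it moved none of the other counts it was fitted for by over 1.5 times. Numbers of empty-vector untreated and day 5 arrays deviated in opposite directions (r = -0.213), and with crossed numbers the counts were 1847 for day 5 in the empty vector, 165 for day 5 in TEL-AML1 cells, and 0 for day 7 against day 5 in each vector.

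Among other settings, quantile normalization, the filter at the 60th percentile, a pseudocount of 1, the mean of probe sets, the trended robust variance, and the fits without genes that follow the stroma list or without distal chromosome 5 and chromosome Y moved no count by over 1.5 times. Centring gave 2 for the response difference at day 5, no filter 5 for that at day 7, every probe set 22 for that at day 5, and a pseudocount of 64 gave 1 for day 7 against day 5 in TEL-AML1 cells. Array weights gave 2600 for TEL-AML1 in untreated cells, 899 at day 7, 468 for day 5 and 2233 for day 7 in TEL-AML1 cells, and 7 for the response difference at day 5. The stroma covariate gave 426 for day 5 in the empty vector, 84 for day 5 and 1461 for day 7 in TEL-AML1 cells, and 9 and 21 for the response differences at day 5 and day 7. With only the compared groups the counts were 2369, 325 and 367 for TEL-AML1 in untreated, day 5 and day 7 cells, 295 for day 7 in the empty vector, 1637 for day 7 in TEL-AML1 cells, and 16 and 3 for the response differences. Without both day 5 replicate 1 arrays they were 369 for TEL-AML1 at day 5, 86 for day 5 in TEL-AML1 cells, and 0 and 3 for the response differences. The causes of these changes were not tested. The main fit pools 1 spread over all groups, although replicates lay closer together in untreated than in treated cells. Its counts for untreated and treated cells are therefore not on an equal footing.

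Among named gene calls, values that changed sign did so with the stroma covariate, for day 5 in the empty vector: Sparc (-0.125), Cxcl12 (-0.084), Ebf1 (-0.246), Cnn3 (-0.042), Pparg (-0.174), Lpl (-0.466) and Lcn2 (-0.368), which the covariate lowers by construction where a gene follows the stroma list. Sign changes of genes that were not called were not counted. That covariate ended 20 other named calls, the compared groups alone ended 47 and the fit without both day 5 replicate 1 arrays 31. Of the camera results, 77 lost their call with an estimated correlation and 223 did not change. By fry 53 lost and 13 gained a call, with the stroma covariate 25 and 14, without a filter 3 and 7, with the block over all arrays 2 and 3, and within each condition 0 and 4. Array brightness limits the dimmest genes, since 15 B lineage genes lay under the filter.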

Other observations

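The lists and their tests in this part were fixed beforehand, and the choice of which of them to describe here was made after the results were seen.

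Of 19 sterol synthesis genes, 4 fell at day 5 in empty-vector cells (7 adjusted over the list alone, median -0.29, camera adjusted p = 0.0207, adjusted p = 0.658 with an estimated correlation), and 6 fell and 1 rose at day 7 (7 and 1 adjusted over the list alone, camera adjusted p = 0.0413, adjusted p = 0.582 with an estimated correlation). In TEL-AML1 cells at day 5 none of them passed (0 adjusted over the list alone, camera adjusted p = 0.11, 7.72e-05 with the stroma covariate, and 0.791 with an estimated correlation and no covariate). At day 7 none passed either (4 down adjusted over the list alone, median -0.17, camera adjusted p = 0.0325, adjusted p = 0.681 with an estimated correlation). Hmgcs1, at the start of the pathway, stood at -0.74 ± 0.17 at day 7 in the empty vector, and its adjusted p of 0.0164 became as much as 0.117 without either untreated array or day 7 replicate 1, and 0.101 with only the compared groups. Of 25 hypoxia and glycolysis genes, 7 fell and 1 rose by day 7 in the empty vector (7 and 2 adjusted over the list alone, camera adjusted p = 0.0413, adjusted p = 0.582 with an estimated correlation) and 4 fell and 1 rose in TEL-AML1 cells (5 and 2 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.578 with an estimated correlation).

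Of 23 stem and progenitor genes, 4 rose and 1 fell at day 5 in the empty vector (4 and 1 adjusted over the list alone, camera adjusted p = 0.0207, adjusted p = 0.503 with an estimated correlation), 7 rose at day 7 (8 adjusted over the list alone, camera adjusted p = 0.00719, adjusted p = 0.582 with an estimated correlation), and 6 rose at day 7 in TEL-AML1 cells (8 up and 1 down adjusted over the list alone, camera adjusted p = 0.00632, adjusted p = 0.334 with an estimated correlation). In TEL-AML1 cells at day 5, 1 rose (1 adjusted over the list alone, camera adjusted p = 0.565). Angpt1 reached 1.56 ± 0.18 in TEL-AML1 cells at day 7 (adjusted p = 0.000857). Of 20 adhesion and homing genes, 4 were up and 1 down at day 5 in the empty vector and 5 and 1 at day 7 (7 and 1 on each day adjusted over the list alone, camera adjusted p = 0.00367 and 0.00736, adjusted p = 0.129 and 0.179 with an estimated correlation) and 6 up and 2 down at day 7 with TEL-AML1 (9 and 2 adjusted over the list alone, camera adjusted p = 0.00632, adjusted p = 0.179 with an estimated correlation). Targets of JAK and STAT signalling had 3 of 20 up and 1 down at day 7 in TEL-AML1 cells (7 and 1 adjusted over the list alone, camera adjusted p = 0.00224, adjusted p = 0.206 with an estimated correlation), and lymphoid priming genes 1 of 13 up (1 adjusted over the list alone, camera adjusted p = 0.0325, adjusted p = 0.671 with an estimated correlation). With the stroma covariate, lymphoid priming genes had medians of 0.311 at day 5 and 0.22 at day 7 in the empty vector and 0.251 at day 5 in TEL-AML1 cells (adjusted p = 0.0114, 0.0234 and 0.02). Without it the adjusted p was 0.206, 0.0982 and 0.565, and 0.663, 0.582 and 0.824 with an estimated correlation. Granulocyte genes had 4 of 17 up at day 5 in the empty vector (4 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.408 with an estimated correlation), with adjusted p = 0.125 without a filter and 0.167 with the stroma covariate. Runx1 stood at 0.49 ± 0.11 in empty-vector and 0.46 ± 0.11 in TEL-AML1 cells at day 7 (adjusted p = 0.014 and 0.0274). These became as much as 0.0889 without either untreated array or day 7 replicate 1 of the empty vector, and 0.197 without any untreated array of either vector or any day 7 array of TEL-AML1. With only the compared groups the former was 0.0683, and with median centring the latter was 0.0685.

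Some list calls turned on the replicate number as a block over all arrays. Erythroid genes in the empty vector had adjusted p = 0.0774 at day 5 and 0.0616 at day 7 without the block and 0.0328 and 0.033 with it, and immediate early genes at day 7 had 0.061 and 0.0445. An estimated correlation without the block gave adjusted p = 0.658, 0.582 and 0.582 in that order. In TEL-AML1 cells at day 5, mast cell, basophil and eosinophil genes (2 of 23 down, 3 adjusted over the list alone) had 0.0311 without the block and 0.0546 with it, and adipocyte genes (0 of 13, 0 adjusted over the list alone) 0.0477 and 0.0579. For these 2 lists the adjusted p was 0.42 and 0.42 with an estimated correlation, and 0.199 and 0.881 with the stroma covariate.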
